A study of Arabidopsis thaliana with 4 samples.

How the data were processed

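RNA from shoots of Arabidopsis thaliana (accession Col-0) was measured on 4 Affymetrix arrays, 2 from plants overexpressing bHLH122, a basic helix-loop-helix transcription factor, and 2 from wild type. Per the labels' protocols, seeds were stratified for 96 h, grown for 1 week on medium and 2 weeks in soil, and total RNA was extracted with Trizol, treated with DNase and labelled with biotin by in vitro transcription. The source labels describe the overexpressor arrays as independent lines, whereas both titles carry line number 18; the arrays were therefore treated as 1 group, and line was no term of the model. Nothing in the labels says that the wild-type arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

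The deposited table holds 1 signal intensity per probe set and array on a linear scale. RMA is the tool named per the submitters' processing notes; its version and software are not given in the sources used here, and neither is the step that returned its values to a linear scale. The log2 of the deposited intensity was taken before every test, and no background correction or normalization was added. The table has 22810 probe sets, of which 64 are controls and were left out of the tests, leaving 22746. Median signal was 40.8 and 40.2 on the overexpressor arrays and 39.2 and 40.0 on the wild-type arrays, and the number of arrays limits the precision of every value. No detection calls were used, so a group near the lower end of the signal range understates a change.

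Genes were named from the platform annotation supplied with the table. It gives 1 gene for 13513 of the tested probe sets and several for 503, and 8730 are not named here. Symbols were updated through Entrez identifiers in the TAIR10.1 gene table, which matched 13436 of the 13513. That table also gave the order of plastid genes and the gene lengths, which span introns. No probe set is paired with bHLH122 or with the ABA 8'-hydroxylase genes CYP707A1 to CYP707A4 in the annotation, so these transcripts are not analysed here and the targeted gene gives no check of the labels.

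The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided, Benjamini-Hochberg adjustment over the 22746 probe sets, threshold 0.05). The fit had 2 residual degrees of freedom per probe set and 4.24 prior degrees of freedom. A second count took probe sets changed at least 2-fold with both overexpressor arrays on the same side of both wild-type arrays. This design, most of the settings tried beside it, 31 gene lists with 385 different genes and the rule for named genes were fixed before the data were examined. The rule took bHLH122 and its relatives, CYP707A1 to CYP707A4, the 10 highest and 10 lowest log2 fold changes past the threshold with 1 gene and the groups apart, a gene counting once by its brightest probe set, and up to 4 members with the smallest p of each list. Only 41 of the list genes have a named probe set. Lists with at least 5 measured members were tested with camera (preset correlation 0.01). Of the lists, 1 reached that number, and 6 reached 3. With an estimated correlation, camera also takes no more than the 2 residual degrees of freedom. Its p can then rise even where the estimate is below the preset. Members of the 10 lists with no measured gene (ABA synthesis, ABA receptors and signalling, guard-cell transport, morning clock, ethylene, oxidative stress, phosphate starvation, cuticle, flower markers and dividing cells) are not analysed here.

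Chosen after seeing the data were a cluster of plastid genes that was described and not tested, 7 other groups of organelle genes, 41 families of genes sharing the letters that open their symbol, the relation of fold change to gene length, and the settings that took only nuclear probe sets, removed the length trend or tested lists with at least 3 measured members. The length trend was removed from each array by lowess (span 0.5 on log2 length, within 4 bins of mean signal) over the 13367 nuclear probe sets with 1 gene and a length, 99.4% of those that could have one. Removal takes out any biological relation to length as well. The settings fixed in advance were quantile normalization, median centring, filters on dim probe sets, an intensity trend with robust hyperparameters, leaving out each array, the replicate number as a block, ordinary statistics without moderation, other thresholds, 1 probe set per gene, and other settings of the list test.

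The fit was tested on simulated data, 20 draws of 22746 probe sets with 200 changed for the comparison of overexpressor with wild type. It recovered on average 0.299% of 1.5-fold changes, 38.7% of 2-fold changes (16.4% to 49.3% between draws) and 81.5% of 4-fold changes (71.2% to 90.9%), with at most 3 false calls in a draw. In the data 5460 probe sets (24.0%) passed, which makes the adjusted threshold laxer than with 200 changed. The simulation also took each probe set's own SD as the true one. These rates and false calls therefore do not carry over to the data. In 200 simulated lists of 10 members, camera gave p under 0.05 for 5.5% of unshifted lists and 100% of those shifted by 0.4. These lists had noise independent between members and no other probe set changed. Both differ from the data, so the shares do not carry over to the lists tested here. For shifts between 3' and 5' signal, probe sets of the same control RNA were averaged, so that each RNA counts once, and the 95% interval of the mean was taken from the t distribution over RNAs, which are not replicates of the plants.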

Results

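Shoots of Arabidopsis plants overexpressing the transcription factor bHLH122 were compared with wild-type Col-0 shoots on 4 arrays, 2 per group. The arrays of a group were close to each other, with r = 0.997 between the overexpressor arrays and r = 0.996 between the wild-type arrays across probe sets, against 0.980 to 0.981 between groups. Probe sets are not independent replicates, so these values describe the arrays only. Between the arrays of a group, 6 probe sets in the overexpressors and 3 in wild type were at least 2-fold apart.

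The question of the design was which transcripts differ when bHLH122 is overexpressed. The largest rises among named genes were in plastid genes for ribosomal proteins: rpl22 rose by 4.42 on the log2 scale (SE 0.10, limma adjusted p = 3.35e-05), rps3 by 3.48, rps19 by 3.09, rpl14 by 2.85, rpl36 by 2.79 and rpl16 by 2.70. The largest falls were in nuclear genes. ORA47, a transcription factor of the AP2/ERF family, had a mean log2 signal of 5.05 ± 0.28 in the overexpressors and 9.35 ± 0.02 in wild type (SD, n = 2 each; log2 fold change -4.30, SE 0.15, limma adjusted p = 9.15e-05). AT4G27654 (-4.23), AT4G29780 (-4.06), the calmodulin-like gene CML38 (-3.46), AT1G05575 (-3.08) and STZ, a zinc finger factor also called ZAT10 (-3.06), followed.

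Beyond the plastid genes, the highest named rises were AT4G09760 (2.35, SE 0.11), AT4G32190 (2.28, SE 0.22), the sucrose-phosphate synthase gene ATSPS4F (2.25, SE 0.11) and AT1G17360 (2.21, SE 0.12). The list of falls was completed by AT1G15010 (-3.004), AT4G27280 (-2.88), AT2G27080 (-2.83) and AT3G01830 (-2.81). The largest SE of a fold change among these 20 genes was 0.22, for AT4G32190 and AT1G15010. CML38, AT4G27654 and AT3G01830 had mean log2 signals of 3.56, 3.55 and 3.39 in the overexpressors, close to the lower quartile of those arrays (3.46 and 3.54). Among probe sets without a gene in the annotation, the largest falls were -4.55 and -4.25 and the largest rises 2.49 and 2.47.

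**Figure D1:**
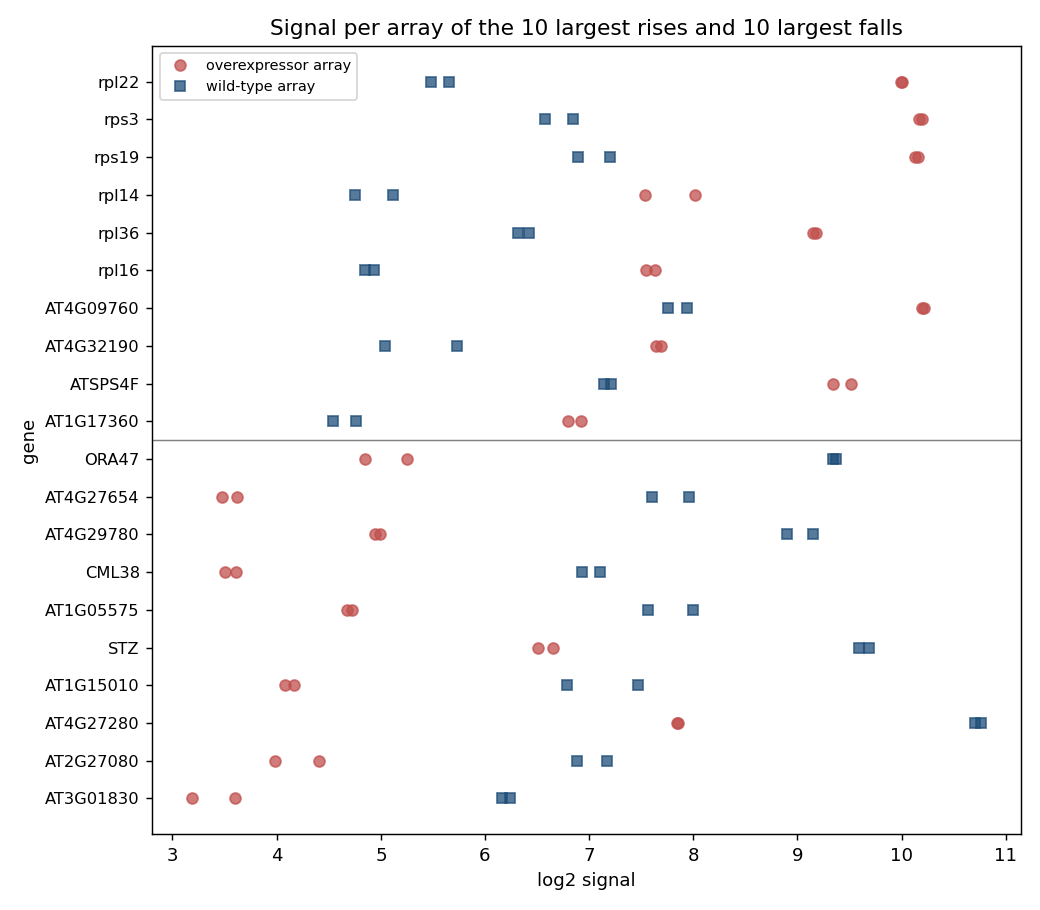
Log2 signal (horizontal axis) of the 10 named genes with the largest rises (above the line) and the 10 with the largest falls (below it); each circle is 1 overexpressor array and each square 1 wild-type array, with no error bars because every array is shown. For every gene both overexpressor arrays lie on the same side of both wild-type arrays, as the rule for naming them required, with log2 fold changes from 4.42 for rpl22 to -4.30 for ORA47.

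In all, 5460 of 22746 probe sets (24.0%) passed the adjusted threshold in limma, 2776 higher and 2684 lower in the overexpressors, and 2912 of them have 1 named gene. At least 2-fold changes with the groups apart were found for 776 probe sets, 364 higher and 412 lower, all past the threshold; chance alone sets the groups apart for 33.3% of probe sets, at any size of change. The other 2 ways to split the 4 arrays gave 0 and 0 such 2-fold changes, but each puts both genotypes into every group and so gives no measure of chance. The count of 5460 depends on sharing variance between probe sets: with ordinary statistics, which share none, 5 probe sets passed, and none of the 20 genes above, whose adjusted p then lay between 0.0669 and 0.141. It fell to 3336 without overexpressor replicate 1, 3586 without overexpressor replicate 2, 3339 without wild-type replicate 1 and 3318 without wild-type replicate 2.

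The departure from wild type was alike on both overexpressor arrays: overexpressor 1 minus wild type 1 and overexpressor 2 minus wild type 2, which share no array, correlated across probe sets with r = 0.80 and rho = 0.66, and 71.5% of probe sets had the same sign. The crossed pairs gave r = 0.81, rho = 0.68 and 71.9%.

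Among genes of photosynthesis, 3 of 6 measured nuclear genes rose and none fell, adjusted over all probe sets and likewise adjusted over the list alone. The measured lists are short, so adjusting over a list alone is mild here and below. For comparison, 36.2% of all probe sets had unadjusted p under 0.05 in limma, in either direction. Calls were commoner among bright probe sets. Of the 11373 above the median of mean signal, where the photosynthesis genes named next lie, 4167 passed when adjusted over all probe sets. The share of 3 in 6 is thus no mark of this list by itself. Phosphoribulokinase PRK rose by 0.69 (SE 0.11), sedoheptulose-bisphosphatase SBPASE by 0.44 (SE 0.09) and the Rubisco activase gene RCA by 0.34 (SE 0.10). The antenna gene LHCB4.1 had a log2 fold change of 0.11 (SE 0.10) and did not pass. The list shifted upward by camera in limma (adjusted p = 0.0299; median log2 fold change 0.23), but adjusted p = 0.156 with an estimated correlation. The shift did not pass without overexpressor replicate 1 or wild-type replicate 1. Nor did it pass after quantile normalization (camera adjusted p = 0.0656), or without the probe sets in the lowest quartile (0.0589) or below the median (0.0570) of mean signal. Across settings the camera adjusted p ran from 7.71e-04, with nuclear probe sets only and the length trend removed, to 0.156 with an estimated correlation. It reached 0.238 with lists of 3 or more members and an estimated correlation together. SBPASE and RCA lost their calls when any 1 array was left out, and RCA also after quantile normalization and median centring.

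Of the stomatal lineage regulators, FAMA (0.67, SE 0.10) and SPCH (0.56, SE 0.13) rose, while MUTE (0.30, SE 0.10) did not pass; 3 of 3 passed when adjusted over the list alone. SPCH did not pass without overexpressor replicate 2 (log2 fold change 0.41), wild-type replicate 1 (0.62) or wild-type replicate 2 (0.49). Of the flavonoid genes, DFR, which encodes dihydroflavonol reductase, rose by 0.81 (SE 0.10), and UF3GT (0.32) and 5GT (0.23) did not pass; 2 of 3 passed adjusted over the list alone. In glucosinolate synthesis UGT74B1 rose by 0.38 and BCAT4 (-0.32) did not pass, while adjusted over the list alone 1 was higher and 1 lower. UGT74B1 lost its call when any 1 array was left out.

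In the jasmonate list 2 of 2 measured genes fell, the thionin gene THI2.1 by 2.01 (SE 0.10) and the defensin gene PDF1.2A by 1.49 (SE 0.11), and 2 passed adjusted over the list alone. The senescence-related factor WRKY53 fell by 2.53 (SE 0.10), and WRKY6 (-0.07) did not pass; 1 of 2 passed adjusted over the list alone. In the cold list ZAT10 and COR15B (-0.34, SE 0.10) fell, COR47 (-0.25) and COR15A (0.09) did not pass, and 2 of 4 passed adjusted over the list alone. COR15B lost its call when any 1 array was left out and after quantile normalization (-0.30). ZAT10 is also the 1 measured member of the touch and wound list, where adjusting over the list alone leaves its p unchanged.

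Of the auxin genes, GH3.5 fell by 0.56 (SE 0.13), and GH3.3 (0.41), GH3.1 (-0.17) and IAA29 (-0.06) did not pass; 1 of 4 passed adjusted over the list alone. GH3.5 did not pass without overexpressor replicate 1 (log2 fold change -0.48) or wild-type replicate 2 (-0.43). No measured member passed, over all probe sets or adjusted over the list alone, in the lists for relatives of bHLH122 (bHLH129, 0.04), ABA breakdown (UGT71B6, -0.25), drought response (LTI30, 0.14), photoperiod and the evening clock (GI, -0.26), salicylate (SAG101, -0.19), heat (HSP22, 0.01), iron (PYE, -0.26; bHLH101, 0.29), cytokinin (ARR15, 0.21; ARR16, 0.06), root markers (EXPA7, -0.09) and shoot meristem markers (CLV3, -0.06). The reference genes TIP41 (-0.28), SAND (0.28) and AT4G26410 (-0.40) did not pass over all probe sets, whereas adjusted over the list alone 1 was higher and 2 lower.

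Plastid and mitochondrial genes were grouped after their values were seen. The 7 named plastid genes from rpoA to rps19, which have no other named probe set between them in the TAIR10.1 order, all rose. Their rises ran from 2.01 (rpoA) to 4.42 (rpl22), with a median of 2.85. Genes without a named probe set may lie between them. The unnamed probe set that rose by 2.47 carries an identifier between those of rpoA and rpl36. These 7 genes were grouped because of their rises, so the group was not tested. Of the other 62 plastid probe sets 24 rose, 2 fell and 36 did not pass, with a median of 0.34 (limma camera adjusted p = 1.07e-06; adjusted p = 0.166 with an estimated correlation). The rises included ndhA (1.94, SE 0.10), atpA (1.76, SE 0.38), accD (1.75, SE 0.22) and psaI (1.28, SE 0.11). The overexpressor arrays differed widely for atpA, with log2 signals of 9.96 and 8.68. The falls were psbA (-0.61, SE 0.11) and psaC (-0.63, SE 0.16), and rbcL had a log2 fold change of -0.06 and did not pass.

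**Figure D2:**
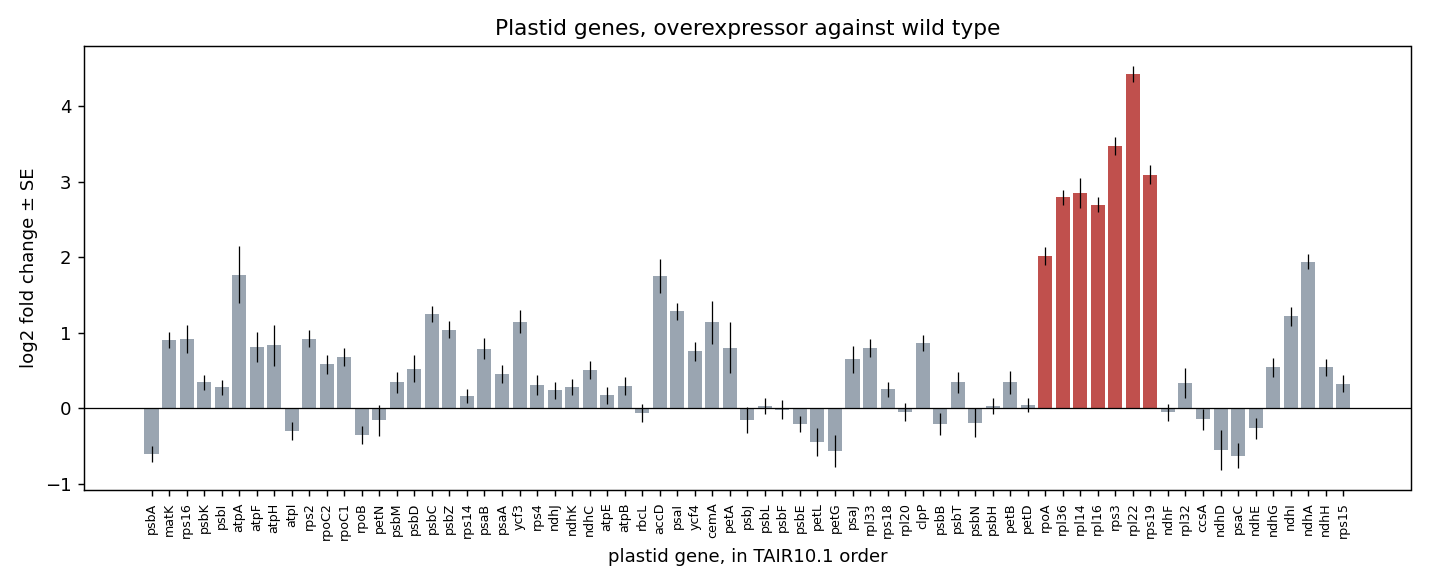
Log2 fold change of overexpressor against wild type (vertical axis, bars, with the SE from limma as error bars, n = 2 per group) for 69 plastid probe sets in the gene order of TAIR10.1 (horizontal axis). The 7 red bars, rpoA to rps19, stand between 2.01 and 4.42, and the tallest grey bar is ndhA at 1.94.

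By complex, 5 of 10 plastid NDH genes rose (camera adjusted p = 0.00463; adjusted p = 0.178 with an estimated correlation), as did 3 of 9 other ribosomal protein genes (adjusted p = 0.00147; 0.178 as the adjusted p with an estimated correlation) and 2 of 6 ATP synthase genes (adjusted p = 0.0385; 0.363 as the adjusted p with an estimated correlation). Of 20 photosystem genes 6 rose and 2 fell (adjusted p = 0.0113; adjusted p = 0.178 with an estimated correlation). None of 6 cytochrome b6f genes passed in limma (camera adjusted p = 0.965, upward; median -0.06). Of 16 mitochondrial genes 6 fell, among them cox1 (-0.97) and cox2 (-0.63), and none rose (median -0.39, camera adjusted p = 0.00147; adjusted p = 0.287 with an estimated correlation).

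Among brighter nuclear probe sets, longer genes were higher and shorter ones lower in the overexpressors. Over all 13367 nuclear probe sets log2 fold change correlated with log2 gene length across genes with r = 0.33 and rose by 0.15 per doubling of length, and in the dimmest quartile r was 0.0938. Among the 6683 nuclear probe sets above the median of mean signal, r was 0.48 and rho 0.49, with a rise of 0.34 per doubling. Genes are not independent replicates. Of these, 49.7% of genes up to 1000 bp fell and 2.32% rose (median -0.41), and 61.3% of those over 6000 bp rose and 0.461% fell (median 0.56). The correlation was 0.46 for overexpressor 1 minus wild type 1 and 0.48 for overexpressor 2 minus wild type 2, against -0.0328 between the overexpressor arrays and -0.00500 between the wild-type arrays.

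**Figure D3:**
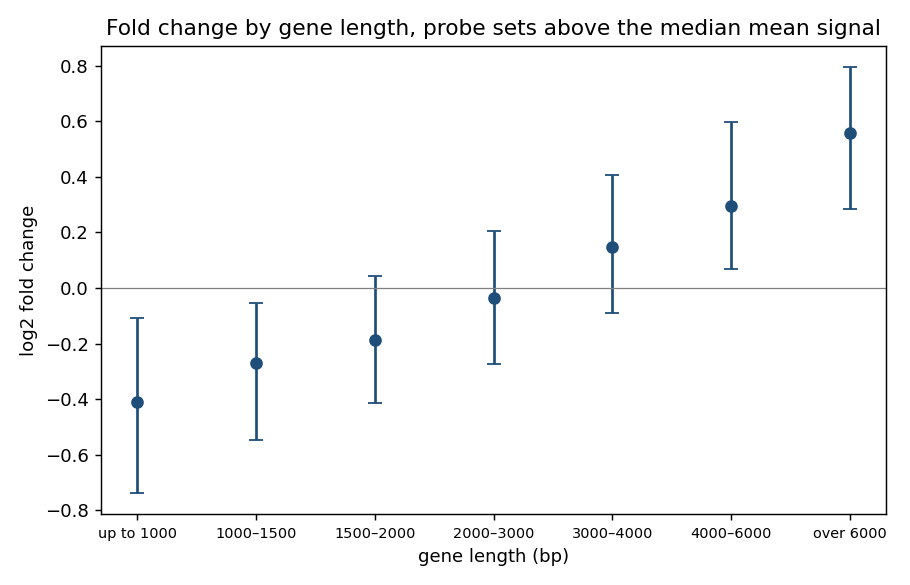
Median log2 fold change of overexpressor against wild type (vertical axis, points) with the lower and upper quartile (bars) by gene length in bp (horizontal axis), over nuclear probe sets above the median of mean signal. The median climbs from -0.41 for genes up to 1000 bp to 0.56 for genes over 6000 bp.

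With the trend removed from the nuclear probe sets, 2101 of 13367 passed in limma, against 2650 before, and 1696 of 2860 calls were kept. All 14 nuclear genes among the 20 largest changes stayed past the threshold, ORA47 at -4.02 and CML38 at -3.19. FAMA (0.54), DFR (0.94), PRK (0.75), WRKY53 (-2.33), THI2.1 (-1.65) and PDF1.2A (-1.10) also passed, whereas SPCH (0.44), RCA (0.31) and COR15B (-0.19) did not. GI (-0.70), LTI30 (0.46), UF3GT (0.50) and 5GT (0.42) passed only with the trend removed or, for UF3GT, also under other alternatives. Control RNA with a poly-A tail, added to the samples before labelling, had a lower mean in the overexpressors on all 24 probe sets (median difference -0.59), with the groups apart on 22. The hybridization controls had a lower mean on all 18 (median difference -0.25), with the groups apart on 13.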

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

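The settings with length, nuclear probe sets or lists of 3 members were chosen after seeing the data; the others were planned. Of the values for single genes, 579 kept their direction and side of the threshold, 64 lost and 18 gained a call, and 13 changed sign. The count of 5460 moved to 3318 to 3586 with 1 array left out (the lone array is assumed to vary like the other group), 5 with ordinary statistics, 2679 with 1 probe set per gene, 2650 with nuclear probe sets of 1 gene, 2101 with the length trend removed, 2240 at an adjusted p under 0.01 and 776 with a 2-fold minimum. Fewer samples, fewer probe sets, a stricter threshold or, for ordinary statistics, unshared variance account for these by construction, except for length removal, where the cause was not tested. With median centring 2575 were higher and 3107 lower, and of the 2-fold changes 320 and 438. With the replicate number as a block 3612 passed; the numbers do not pair the samples (correlation of same-numbered deviations -0.0411). The count of 776 moved to 2973 at 1.5-fold, 192 at 3-fold, 370 with nuclear probe sets and 262 with the length trend removed. The photosynthesis list had camera p of 0.0656 after quantile normalization, 0.0589 and 0.0570 without the lowest quartile and without probe sets below the median of mean signal, 0.0241 to 0.0844 with 1 array left out, and 0.156 with an estimated correlation; the cause was not tested. The correlation of the overexpressor arrays' differences was 0.838 and 0.899 without those dim probe sets and 0.815 for crossed pairs, where the cause was not tested. Signs changed only in genes with no call, and the cause was not tested. With 1 array left out, log2 fold changes ranged from -0.0228 to 0.0465 for HSP22, -0.196 to 0.315 for ARR16, -0.146 to 0.0149 for WRKY6, -0.0276 to 0.108 for bHLH129, -0.413 to 0.0806 for GH3.1, -0.00162 to 0.574 for bHLH101, -0.136 to 0.00858 for CLV3 and -0.262 to 0.0867 for EXPA7. HSP22 was -0.0214 with median centring, and bHLH129 was -0.124 and IAA29 0.153 with the length trend removed. The alternatives for the bHLH122 transcript were not run, since no probe set is paired with it. Without detection calls, how far signal lies above background is unknown, which limits the dimmest genes most.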

Other observations

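Families of genes that share the opening letters of their symbol, 41 with at least 5 measured members, were grouped after seeing the data. By limma's camera with the preset correlation 12 of the 41 passed, 5 higher (TRM, UBP, CRR, SEC and NET) and 7 lower (PRA, CML, PDF, LSM, CLE, PUB and RALFL), and with an estimated correlation 0 passed (lowest adjusted p = 0.543). The 4 described here were chosen after their values were seen. Their estimated correlations were 0.0561 (TRM), -0.124 (CML), -0.0601 (PUB) and -0.212 (CRR), against the preset 0.01. For CML, PUB and CRR, correlated members therefore do not account for the loss with an estimated correlation. That setting leaves 2 residual degrees of freedom, so a family could hardly pass an adjustment over 41, with or without the length trend. Its 0 passes therefore cannot decide about the families. Of 15 TRM genes, 10 rose, among them TRM22 (1.16) and TRM19 (1.06), and none fell (limma camera adjusted p = 1.03e-04; adjusted p = 0.543 with an estimated correlation). Among 7 calmodulin-like CML genes 5 fell, CML37 (-1.52) and CML42 (-0.72) besides CML38, and none rose (camera adjusted p = 0.00800; adjusted p = 0.543 with an estimated correlation). Among 9 PUB genes, which encode U-box ubiquitin ligases, 6 fell, PUB24 (-1.46), PUB23 (-1.21) and PUB25 (-1.11) most, and PUB49 rose by 0.62 (camera adjusted p = 0.0429; adjusted p = 0.543 with an estimated correlation). Of 5 CRR genes, CRR21 (1.64) and CRR28 (0.76), which encode editing factors of plastid NDH transcripts, rose (camera adjusted p = 0.0200; adjusted p = 0.543 with an estimated correlation). With the length trend removed 4 families passed in camera, GSTU among them; the TRM (adjusted p = 0.00227), CRR (0.00244) and PUB (0.0402) families still did, and CML (0.126) did not; with an estimated correlation each then had adjusted p = 0.655.

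All tests below were chosen after the results were seen, and each hypothesis was found and tested on the same data. The first pattern is that longer genes were higher and shorter genes lower in the overexpressors. RNA broken down in wild type far enough to reach the plant control transcripts would lower 3' minus 5' signal in the overexpressors. The test looked for a drop of 0.3 or more, a mark chosen after the results were seen. The mean shift over 3 control genes was -0.0241 (SE 0.0378, 95% interval -0.187 to 0.139). The interval leaves out a drop of 0.3 but not a smaller one. Labelling that copied RNA less fully in wild type would lower 3' minus 5' signal in the added poly-A controls, judged by the same mark. Their 4 RNAs ranged from -0.139 (phe) to 0.503 (lys), with a mean shift of 0.0655 (95% interval -0.408 to 0.539) that cannot decide. A normalization that differs with signal would leave no relation at a like signal, yet the lowest r in the upper 3 of 4 bins of mean signal was 0.37; in the dimmest bin r was 0.0938. Labelling, breakdown that gives a smaller shift or spares short transcripts, another difference in RNA preparation and an effect of bHLH122 itself stay open.

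The second pattern is the 10 largest falls, ORA47, CML38 and STZ among them. The length trend as the whole cause would bring their median to above -0.5, and it was -3.07 before and -3.01 after removal. These genes were picked for their large falls, and brighter genes up to 1000 bp had a median of only -0.41. Removal could therefore hardly have given another outcome. It shows only that the trend is too small to be the whole cause. STZ is known to respond quickly to wounding and touch, so handling or time of harvest that differed between the groups may have lowered these genes, but only 1 member of the touch and wound list has a named probe set. Any such difference would coincide with genotype, so even a fall of the whole list would not tell handling and genotype apart. An effect of bHLH122 is untested.

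The third pattern is the rise of the plastid genes from rpoA to rps19. More plastid RNA or DNA as a whole would raise the other plastid probe sets alike, and their median was 0.34 against at least 2.01 in the cluster. The cluster was picked for its rises, so a lower median elsewhere was set in part by that choice. The comparison speaks only to a like rise of all plastid genes. Of the other 62 probe sets 24 rose, 2 fell and 36 did not pass, so it cannot exclude a smaller general rise. The nuclear length trend would give nuclear genes this short a median of -0.47. It was fitted on nuclear genes only, and the lengths of the plastid transcripts are not known here, so it cannot decide about length. A smaller general rise of plastid RNA or DNA as part of the cause, labelling, another difference in RNA preparation and an effect of bHLH122 stay open. No other biological explanation was tested.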
